A study of Mus musculus with 5 samples.

How the data were processed

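RNA from mouse B9 cells was measured on 5 Affymetrix 3' expression arrays with biotin-labelled targets, 1 array per culture sample: 2 with vemurafenib, 2 with PLX7904 and 1 with DMSO, as the labels group them. Per the labels' protocols, 2.4 µL of a 5 mM compound stock was added to 12 mL of medium for a final 1 µM, and cells were harvested after 17 h. The labels give the vehicle as 0.2% DMSO, whereas the stated volume is 0.02% of the medium, so the vehicle concentration of the control relative to the treated cultures is open.

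The values used are the deposited intensity of each of 45101 probe sets on each array, on a linear scale. Per the submitters' processing notes they were made with MAS5, an algorithm that gives 1 signal per probe set from perfect-match and mismatch probes; its version is not given in the sources used here. In the deposited table the mean of the middle 96% of the values of every array was about 500, which is a scaling of whole arrays and leaves differences between arrays that depend on signal in place. No detection calls were used here, so that dim probe sets carry a signal with no statement on whether it exceeds background. MAS5 signals of dim probe sets vary widely between arrays.

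Genes were named from the platform annotation supplied with the table. Of the probe sets, 34958 had 1 gene symbol, 932 several and 9160 none, and 64 were control probe sets. The gene identifiers of 34754 probe sets matched a reference gene table of assembly GRCm38.p6, and 0 symbols needed updating. Only probe sets with 1 symbol were used, and for a gene with several the one with the highest mean over the 3 group means. This gave 18193 genes, 9010 of them with more than 1 probe set, whose probe sets can disagree. The log2 of the signal plus a pseudocount of 3.34, the 10th percentile of all deposited values, was analysed. Genes with a mean signal of at least 47.4, the median of all values, were tested, 10852 in all. A fold change is on the log2(signal + pseudocount) scale, which understates the change of dim genes.

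A linear model with 3 group means was fitted to all 5 arrays with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend), with 2 residual and 8.27 prior degrees of freedom. The 3 contrasts were vemurafenib minus DMSO, PLX7904 minus DMSO and vemurafenib minus PLX7904, and the last is the test of a difference between the compounds. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene passed at an adjusted p under 0.05. Errors are standard errors and 95% intervals from the same fit. The lone DMSO array has no replicate of its own and takes its variance from the treated groups. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

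The groups, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. There were 31 lists. They covered ERK output, ligands of the EGF receptor family, signalling components, cell cycle, p53, stress and metabolic programmes and cytokines. Others covered matrix, keratinocyte, epithelial and mesenchymal genes, ribosomal proteins, oxidative phosphorylation and markers of other cell types. Lists with at least 5 measured members were tested (3 for the ligands), 27 in all, with limma's camera at a preset correlation of 0.01, adjusted over lists within a contrast. Camera compares a list with all other genes and was repeated with a correlation estimated from the residuals. With 2 residual degrees of freedom that estimate is imprecise, and no list passed with it in any contrast. That version also takes its p-values from a t distribution with the 2 residual degrees of freedom. For G2/M between the compounds the camera p went from 1.3e-17 to 0.0109, although the estimated correlation of -0.033 was below the preset. Failing it therefore cannot tell a correlated list from one limited by these degrees of freedom. For each list genes were also adjusted over the list alone. The naming rule selected, per contrast, the 10 largest and 10 smallest log2 fold changes among genes that passed and whose arrays did not overlap. Where none passed, these were completed to 5 by the smallest p. It also selected all members of the ERK output and ligand lists, and Hras and Braf. From other lists that passed or held at least 2 called genes it took up to 2 called members at either end. Unnamed gene models were passed over. The text gives only part of the genes selected, and the rule did not fix which part.

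Alternatives covered the pseudocount (none, or the 25th percentile), the filter (none, or the 75th percentile), quantile normalization, median centring and cyclic loess, eBayes without a trend or with robust fitting, the mean of all probe sets of a gene, leaving out probe sets that may match several transcripts (those with the suffix x, s or a), a block for the replicate number, a fit to the 4 treated arrays, leaving out each treated array in turn, other thresholds, and fry. The fit was tested on simulated data with 200 changed genes among 10852. Noise was drawn for each gene from the variance that this same fit had given it. The simulation therefore cannot test the intensity trend, and the shares recovered hold only if those variances are right. For vemurafenib against DMSO it recovered 55.2% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 89.4% of those changed 4-fold, and called 21 unchanged genes. For vemurafenib against PLX7904 the shares were 71.6%, 89.6% and 98.5%, with 16 unchanged genes called, and for PLX7904 against DMSO, where nothing was changed, 1 gene was called. Of 100 simulated unchanged lists of 25 genes 3 had a camera p under 0.05 at the preset correlation and 0 with an estimated one. Of 100 lists raised by 0.3 all did in both. These p-values were not adjusted over lists, unlike those of the real lists, and the simulated genes varied independently. The simulation therefore does not show how often a real list would pass with an estimated correlation, nor how correlated lists behave. The values expected from the shared DMSO array, and the overlap of calls expected from the shared vemurafenib arrays, came from 100 simulations of unchanged groups each. Genes with no probe set of their own, among them Hras, Areg and Ccnb1, were not analysed here.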

Results

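Transcript levels were measured in B9 cells, a mouse line from a cutaneous squamous cell carcinoma whose genotype is given as HRAS-Q61L, an activating change in the RAS protein upstream of RAF kinases. The cells were kept for 17 h with 1 µM vemurafenib (PLX4032), with 1 µM PLX7904 or with the vehicle dimethyl sulfoxide (DMSO). Vemurafenib is an inhibitor of mutant BRAF that can raise MAPK signalling in cells with mutant RAS, and PLX7904 is a BRAF inhibitor described as a paradox breaker, meaning one intended not to do so. The data comprised 5 arrays, 2 for vemurafenib, 2 for PLX7904 and 1 for DMSO, and their number limits the precision. The labels call them biological replicates without saying more about the cultures, so p-values measure the spread between these arrays. The lone DMSO array was assumed to vary like the treated arrays, and both comparisons with DMSO rest on it. The median signal of an array lay between 44.1 and 51.9. Over the 10852 genes tested, log2 signals of the 2 vemurafenib arrays correlated at r = 0.990 and those of the 2 PLX7904 arrays at r = 0.989. The DMSO array correlated at r = 0.990 with each PLX7904 array and at 0.980 to 0.981 with the vemurafenib arrays. Braf, the kinase both compounds target, did not pass in any comparison, with a log2 difference of -0.07 between vemurafenib and DMSO (SE 0.18, adjusted p = 0.848). Hras was not analysed here.

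The first comparison, of vemurafenib with DMSO, addressed how cells with mutant HRAS respond to a BRAF inhibitor of the first class. Transcripts that RAS-ERK signalling induces rose. Dusp5, a nuclear phosphatase that inactivates ERK, rose 3.92-fold (95% interval 3.33 to 4.62), and Egr1, an immediate early transcription factor, rose 3.97-fold (3.09 to 5.11), in 2 vemurafenib arrays against 1 DMSO array. Spry2, a feedback inhibitor of receptor tyrosine kinase signalling, rose 3.15-fold (2.63 to 3.77). Of the 33 measured members of the ERK output list, 15 rose and 0 fell. Adjusted over the list alone, 20 rose. The list's median log2 fold change was 0.37, with 28 members above 0, and it passed limma's camera test (adjusted p = 1.0e-12). The adjusted p = 0.164 with an estimated correlation did not pass. Plaur (the urokinase receptor, 2.04-fold), Fos (1.87-fold), Phlda1 (1.53-fold) and Dusp6 (1.44-fold) were among those that rose. Myc (log2 0.05, SE 0.10), Ccnd1 (0.16, SE 0.07), Etv4 (0.27, SE 0.16) and Etv5 (-0.19, SE 0.14) were among the 18 members that did not pass. The Ccnd1 value depends on the probe set: an equally bright one (signal 14250, against 14110 for the one used) read 0.32. A dimmer one (signal 6287) read 0.18. Egr3 rose 2.52-fold from its brightest probe set, but its call ended with the mean of all its probe sets (log2 0.65).

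The ligands of the EGF receptor family rose as a group. Hbegf rose 2.37-fold (95% interval 2.13 to 2.64, adjusted p = 6.23e-06), Tgfa 1.79-fold (1.53 to 2.09) and Ereg 1.54-fold (1.34 to 1.78). Btc rose 3.03-fold at a low mean signal of 107 (1.86 to 4.95), a call that ended without the filter on signal. Nrg1 was 1.38-fold higher and did not pass (adjusted p = 0.0665). Of the 5 ligands measured, 4 rose, and all 5 did when adjusted over the list alone. The median log2 fold change was 0.84 (camera adjusted p = 2.21e-07, and adjusted p = 0.164 with an estimated correlation). Averaging all probe sets of a gene ended the calls of Tgfa (log2 0.44) and Btc (1.40).

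**Figure D1:**
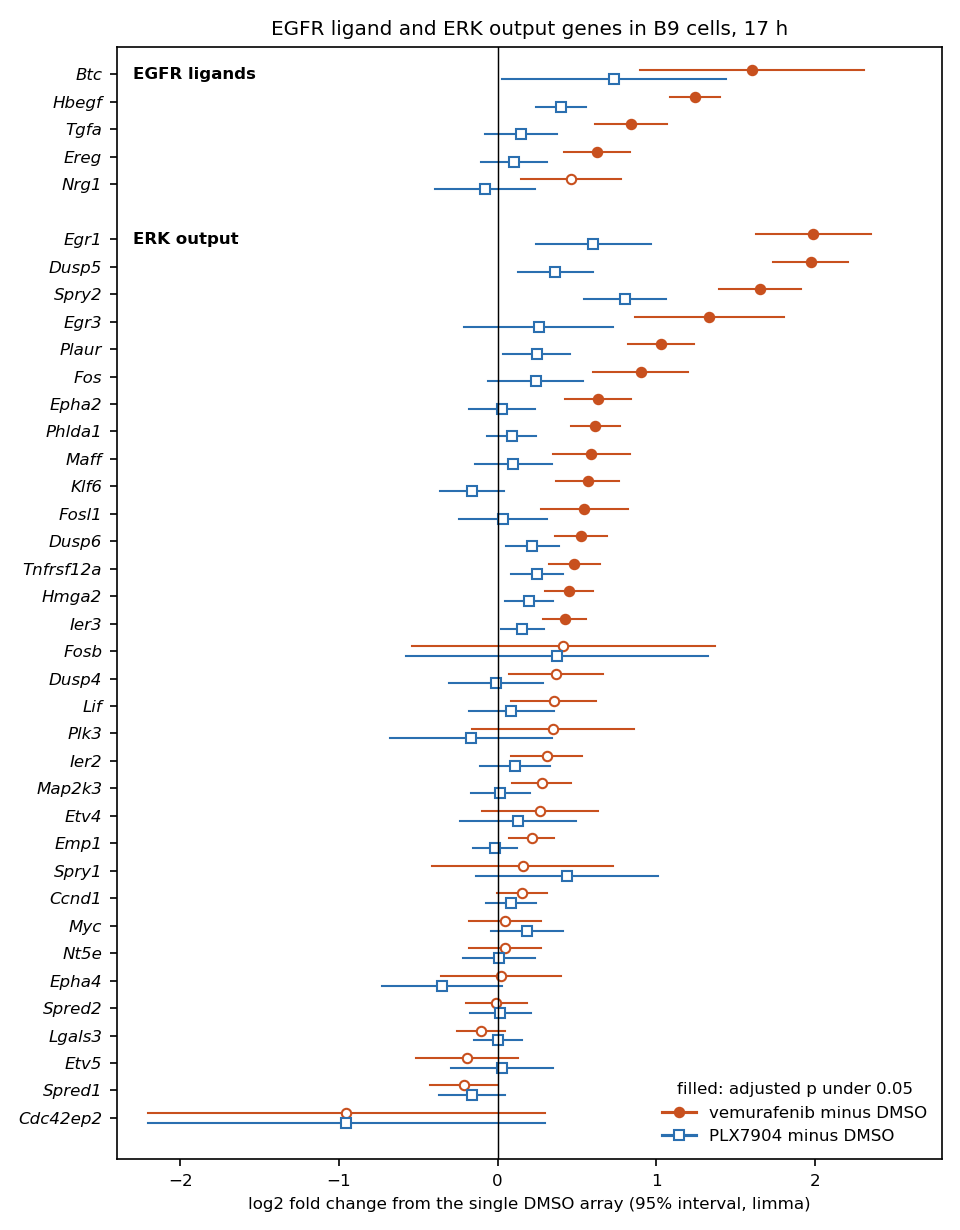
Log2 fold change from DMSO of each measured ERK output gene and ligand of the EGF receptor family, for vemurafenib and for PLX7904. Bars are 95% intervals from limma (2 arrays for each compound, 1 for DMSO). Dusp5, Egr1 and Spry2 lie farthest right with vemurafenib, at 1.97, 1.99 and 1.66, and at 0.36, 0.60 and 0.80 with PLX7904.

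Cell cycle transcripts fell with vemurafenib. Of 25 measured genes of G2/M and mitosis, 17 fell and 0 rose (20 fell when adjusted over the list alone), and none of the 25 lay above 0. Kif11, a spindle motor, was 1.96 times lower (95% interval 1.59 to 2.42) and Nusap1, a spindle microtubule protein, 1.65 times lower (1.42 to 1.90). Of 25 genes of G1/S and DNA replication, 12 fell and 0 rose (16 fell when adjusted over the list alone). Uhrf1, which maintains DNA methylation behind the fork, was 1.70 times lower (1.47 to 1.96) and Mcm2, a subunit of the replicative helicase, 1.64 times lower (1.38 to 1.96). The medians were -0.42 for G2/M (camera adjusted p = 2.54e-10) and -0.38 for G1/S (8.5e-08), each with adjusted p = 0.164 with an estimated correlation. Cdkn1a, the cyclin-dependent kinase inhibitor p21, rose 2.51-fold (2.02 to 3.12). It is 1 of 17 p53 targets measured, of which 2 rose and 3 fell (3 and 4 when adjusted over the list alone), and that list did not pass (adjusted p = 0.541). Mdm2 rose 1.75-fold, while Fas, a death receptor gene, was 6.51 times lower at a mean signal of 108 (3.01 to 14.1) and Sesn1 1.83 times lower. With the mean of all probe sets the calls of Kif11 (log2 -0.46), Nusap1 (-0.73), Mdm2 (0.56) and Sesn1 (-1.04) ended.

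Chaperones of the endoplasmic reticulum rose, 10 of 18 members with 0 lower (12 when adjusted over the list alone), at a median log2 fold change of 0.36. Manf, a secreted stress-induced factor, rose 1.41-fold (95% interval 1.26 to 1.56) and Sdf2l1 1.5-fold (1.27 to 1.78). Camera gave adjusted p = 1.43e-08 for this list, and adjusted p = 0.164 with an estimated correlation. Of 16 genes of matrix proteolysis, 6 rose and 1 fell (7 and 1 when adjusted over the list alone). The stromelysin Mmp10 rose 3.38-fold (2.68 to 4.26) and Mmp1b 2.98-fold (2.45 to 3.63), while the protease inhibitor Timp3 was 3.69 times lower (2.76 to 4.93). That list had adjusted p = 0.0033, adjusted p = 0.368 with an estimated correlation, and adjusted p = 0.0867 with fry, which tests whether a list's genes move on balance one way. Of 19 genes of glycolysis and hypoxia, 4 rose and 1 fell (5 and 2 when adjusted over the list alone; adjusted p = 0.011, and 0.337 as the adjusted p with an estimated correlation). Ndrg1 rose 1.82-fold (1.57 to 2.10) and the angiogenic factor Vegfa 1.59-fold (1.31 to 1.92). The median of 0.12 was 0.135 after quantile normalization (adjusted p = 0.0761), 0.142 after cyclic loess (adjusted p = 0.0635) and 0.101 without probe sets that may match several transcripts (adjusted p = 0.0675), so that the call ended while the shift stayed about as large.

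The keratinocyte lists passed as higher. Of 17 differentiation genes, 4 rose and 0 fell (4 and 1 when adjusted over the list alone), among them Ivl, the cornified envelope precursor involucrin, at 2.77-fold (95% interval 2.29 to 3.35) and Sprr1a at 2.46-fold (2.04 to 2.96). Of 14 basal keratinocyte genes, 5 rose and 0 fell (7 and 2 when adjusted over the list alone), with the laminin-332 subunits Lama3 at 2.35-fold (2.10 to 2.63) and Lamb3 at 2.31-fold (2.01 to 2.65). Of 8 simple epithelial and wound keratins, 3 rose and 1 fell (4 and 1 when adjusted over the list alone). Krt18 rose 1.62-fold (1.48 to 1.79) and Krt6b was 1.42 times lower (1.24 to 1.62). Camera gave adjusted p = 0.0414 for differentiation, 9.85e-04 for basal and 0.0275 for simple and wound keratins. The adjusted p with an estimated correlation was 0.362, 0.271 and 0.370 in that order. The basal list's median of 0.24 turned to -0.08 without probe sets that may match several transcripts, and Lama3's call ended with the mean of all its probe sets (log2 0.90). The differentiation median of 0.07 was 0.0695 after quantile normalization (adjusted p = 0.0742), 0.0877 after cyclic loess (adjusted p = 0.0603), 0.133 with median centring (adjusted p = 0.056) and 0.0045 without the filter on signal (adjusted p = 0.0626), and its call ended in each. Its call also ended without the intensity trend (adjusted p = 0.0829) and with fry (adjusted p = 0.114). The simple and wound keratins went from a median of 0.20 to 0.0808 after quantile normalization (adjusted p = 0.447) and 0.0817 after cyclic loess (adjusted p = 0.374). Their call also ended without the intensity trend or with the filter at the 75th percentile (adjusted p = 0.0701 for each), without probe sets that may match several transcripts (adjusted p = 0.0796) and with fry (adjusted p = 0.0891).

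Among 22 inflammatory genes 3 rose and 6 fell (7 and 9 when adjusted over the list alone), and the list did not pass (adjusted p = 0.843). The monocyte chemokine Ccl2 was 2.76 times lower (95% interval 2.38 to 3.21) and the macrophage growth factor Csf1 2.72 times lower (2.10 to 3.52, a call that ended with the mean of all probe sets, log2 -1.11). The interleukin subunit Il23a rose 2.48-fold (2.02 to 3.05) and the neutrophil chemokine Cxcl2 1.70-fold (1.55 to 1.88). Of 15 ribosomal protein genes 3 rose (13 when adjusted over the list alone), at a median of 0.21 (adjusted p = 2.3e-07, and adjusted p = 0.362 with an estimated correlation). Of 20 genes of oxidative phosphorylation 1 rose, also over the list alone, at a median of 0.08 (adjusted p = 0.0365, and adjusted p = 0.449 with an estimated correlation). Bright genes read higher on the vemurafenib arrays: the median difference from DMSO was -0.18 in the dimmest 25% of genes and 0.16 in the brightest 2%. After quantile normalization the ribosomal median was -0.0041 (adjusted p = 0.763) and that of oxidative phosphorylation -0.05 (adjusted p = 0.491), and after cyclic loess they were 0.04 (adjusted p = 0.307) and -0.04 (adjusted p = 0.592). Both calls also ended without probe sets that may match several transcripts (adjusted p = 0.144 and 0.114), though the medians stayed as large (0.205 and 0.0795). With fry, which uses the same fold changes, they ended too (adjusted p = 0.114 and 0.193). The oxidative phosphorylation list also no longer passed without the intensity trend (adjusted p = 0.0829), with the filter at the 75th percentile (adjusted p = 0.108), or without vemurafenib replicate 1 (median 0.06, adjusted p = 0.13) or replicate 2 (0.11, adjusted p = 0.0503).

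The other 13 lists tested did not pass. Of 15 targets of YAP and SRF 3 fell (2 rose and 4 fell when adjusted over the list alone; median log2 -0.16, adjusted p = 0.0712), among them Thbs1, the matrix protein thrombospondin-1, at 2.19 times lower (95% interval 1.88 to 2.55) and Ccn2 at 1.5 times lower (1.26 to 1.77). That list passed after quantile normalization (adjusted p = 0.0242), after cyclic loess (adjusted p = 0.0205) and with fry (adjusted p = 0.0046), and also without vemurafenib replicate 1 (median -0.16, adjusted p = 0.0285) or replicate 2 (-0.12, adjusted p = 0.0372). Of 8 interferon-stimulated genes 1 fell (adjusted p = 0.0875), of 17 cholesterol synthesis genes 2 rose and 1 fell (0.0688), and of 14 components of the RAS-RAF-MAPK cascade 1 rose (0.0975). The interferon-stimulated list passed as lower without the intensity trend (median -0.43, adjusted p = 0.0175), and cholesterol synthesis as higher with median centring (0.156, adjusted p = 0.0366) or without the filter on signal (0.0885, adjusted p = 0.0471). Targets of NRF2 (0.0975), ATF4 (0.271) and MYC (0.843) did not pass, nor did apoptosis regulators (0.134), mesenchymal genes (0.636) or epithelial junctions (0.808). A list on receptor tyrosine kinase expression after MAPK inhibition, which also held other genes such as Irs2, Klf9 and Foxo1, did not pass either (0.430). This mixed list passed with fry (median -0.18, adjusted p = 0.0144), with 1 of 17 members higher and 4 lower. For NRF2 targets and hair follicle genes the mean was below 0 and the median above it, and for the inflammatory and MYC lists the median was below 0 while camera pointed up. Of markers of other cell types, immune cells (1 of 6 higher, Coro1a, 1.88-fold, adjusted p of the list 0.505) and hair follicle and sebocyte genes (0 of 7 called, 0.733) did not pass. Melanocyte, fibroblast and endothelial markers and targets of the aryl hydrocarbon receptor had 2, 4, 3 and 3 members past the filter and were not tested with camera. With fry the aryl hydrocarbon receptor targets passed (median log2 -0.36, adjusted p = 0.0315), with 1 of the 3 members above 0. Fibroblast (adjusted p = 0.0642) and endothelial markers (adjusted p = 0.175) did not pass with fry.

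In all, 589 genes were higher and 565 lower with vemurafenib than with DMSO, 10.6% of the genes tested, and 103 and 91 of these changed at least 2-fold. Brighter genes among those with the largest changes were Il24, a cytokine of the interleukin-10 family (4.74-fold, 95% interval 3.93 to 5.72), Nppb, the precursor of B-type natriuretic peptide (4.14-fold, 3.66 to 4.69), and Trex2, a DNA exonuclease of keratinocytes (4.19-fold, 3.19 to 5.50). Sostdc1, a secreted antagonist of BMP and Wnt signals, was 5.83 times lower (4.86 to 7.01) and Cyp1b1, a cytochrome P450 that the aryl hydrocarbon receptor induces, 6.06 times lower (4.92 to 7.46). Ptn, the growth factor pleiotrophin, was 6.0 times lower (4.16 to 8.67) and Acta2, smooth muscle actin, 4.88 times lower (3.65 to 6.54). With the mean of all probe sets the calls of Cyp1b1 (log2 -1.29) and Acta2 (-0.81) ended. The gene with the largest rise, AI854703, read 6.37 on the DMSO array, and its 12.0-fold change has an interval of 4.78 to 30.0. AI854703 was also higher with vemurafenib than with PLX7904. That call ended without the pseudocount (log2 1.86, adjusted p = 0.0541) or without the filter on signal (1.75, adjusted p = 0.086). Pmel (5.57-fold), Tmem198 (4.85-fold) and Prrt1 (4.82-fold) were dim too and, unlike AI854703, low on the DMSO array alone. Their log2 values with vemurafenib differed from those with PLX7904 by 0.33, 0.03 and 0.42, and none of these differences passed. The call of Tmem198 ended without vemurafenib replicate 2 (log2 1.70), and the calls of Tmem198 and Prrt1 ended without the filter on signal. Median centring of each array gave 850 higher and 384 lower genes, so that 68.9% of calls were higher in place of 51%. The counts rest on limma's trend of variance with intensity: without it 26 genes were higher and 17 lower, and 40 of the 1154 calls were kept.

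The second comparison, of PLX7904 with DMSO, addressed whether a BRAF inhibitor of the other class moves the same cells. With limma no gene passed: 0 were higher and 0 lower at an adjusted p under 0.05, against 722 genes at an unadjusted p under 0.05 where 543 are expected by chance. Without limma's intensity trend the count was also 0, with 610 genes at an unadjusted p under 0.05, and robust fitting called 1 higher and 2 lower. The median unadjusted 95% interval of a gene reached 0.31 on the log2 scale to either side, and larger changes than this also missed the threshold adjusted over all genes. The smallest adjusted p, 0.0563, belonged to Tpt1, which encodes a growth-related calcium-binding protein (1.41-fold, 95% interval 1.27 to 1.55), to Cyp1b1 (2.06 times lower, 1.67 to 2.53) and to Sec24b, a vesicle coat subunit (2.04 times lower, 1.66 to 2.51). Spry2 was 1.75-fold higher (1.46 to 2.09, adjusted p = 0.1), Hbegf 1.32-fold (1.18 to 1.47, 0.216), Dusp5 1.29-fold (1.09 to 1.52, 0.493) and Egr1 1.52-fold (1.18 to 1.95, 0.462). Without vemurafenib replicate 1, 14 genes were higher and 15 lower, and without vemurafenib replicate 2, 12 and 15. These arrays enter this comparison only through the variance that all groups share.

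Some lists shifted a little with PLX7904 although no member passed over all genes. The ERK output list had a median log2 fold change of 0.09 with 26 of 33 members above 0 (camera adjusted p = 2.54e-04, and adjusted p = 0.447 with an estimated correlation), and 1 member rose when adjusted over the list alone. Ligands of the EGF receptor family had a median of 0.15 (adjusted p = 0.0071, and adjusted p = 0.447 with an estimated correlation), with 1 higher when adjusted over the list alone. The G2/M list lay at 0.09 with 21 of 25 members above 0 (adjusted p = 0.0090, and adjusted p = 0.447 with an estimated correlation), and the G1/S list at 0.01 (adjusted p = 0.961). The ligands no longer passed without the filter on signal (0.103, adjusted p = 0.163), with the filter at the 75th percentile (0.125, adjusted p = 0.058), with the mean of all probe sets (0.103, adjusted p = 0.341) or with fry (adjusted p = 0.119), nor did G2/M with fry (adjusted p = 0.185). Without PLX7904 replicate 2 the ligands (0.21, adjusted p = 0.0624) and G2/M (0.07, adjusted p = 0.0624) no longer passed. Targets of YAP and SRF had a median of -0.19 (adjusted p = 3.25e-05), 4 of 15 being lower when adjusted over the list alone. Epithelial junction genes lay at -0.18 (adjusted p = 0.0225) with 1 of 14 higher and 2 lower when adjusted over the list alone. Both had adjusted p = 0.447 with an estimated correlation, and with fry adjusted p = 0.113 and 0.119. The junction call also ended without the intensity trend (adjusted p = 0.107) and without probe sets that may match several transcripts (-0.132, adjusted p = 0.0616). Ccn2, a matricellular protein that YAP induces, was 1.35 times lower (95% interval 1.14 to 1.59, adjusted p = 0.415) and the desmosomal Jup 1.30 times lower (1.09 to 1.56, adjusted p = 0.509). Ribosomal protein genes lay at 0.21, all 15 above 0 and 14 higher when adjusted over the list alone (adjusted p = 4.48e-17, and adjusted p = 0.447 with an estimated correlation). After quantile normalization their median was 0.02 (adjusted p = 0.399), and with fry they had adjusted p = 0.237. After cyclic loess the median was 0.09 with all 15 above 0, and the list still passed camera (adjusted p = 8.9e-07). Oxidative phosphorylation lay at 0.05 with 1 of 20 higher when adjusted over the list alone (adjusted p = 0.0014, and adjusted p = 0.610 with an estimated correlation), and after quantile normalization that list did not pass (adjusted p = 0.788), nor after cyclic loess (adjusted p = 0.837) or with fry (adjusted p = 0.333). The other 19 lists tested did not pass, at adjusted p from 0.112 to 0.961. Among lists that did not pass, camera pointed up while median and mean were below 0 for NRF2 targets, cholesterol synthesis, glycolysis, inflammatory, mesenchymal, immune and hair follicle genes, and the mean was below 0 and the median above it for G1/S and interferon-stimulated genes. After quantile normalization the simple epithelial and wound keratins (median log2 -0.11, adjusted p = 0.0095) and keratinocyte differentiation (-0.11, adjusted p = 0.0498) passed as lower, as they did after cyclic loess (-0.08, adjusted p = 0.0156, and -0.13, adjusted p = 0.0365). Without PLX7904 replicate 2 differentiation also passed (-0.23, adjusted p = 0.0407) and epithelial junctions did not (-0.20, adjusted p = 0.0574), and without PLX7904 replicate 1 the endoplasmic reticulum chaperones passed as higher (0.09, adjusted p = 0.012).

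**Figure D2:**
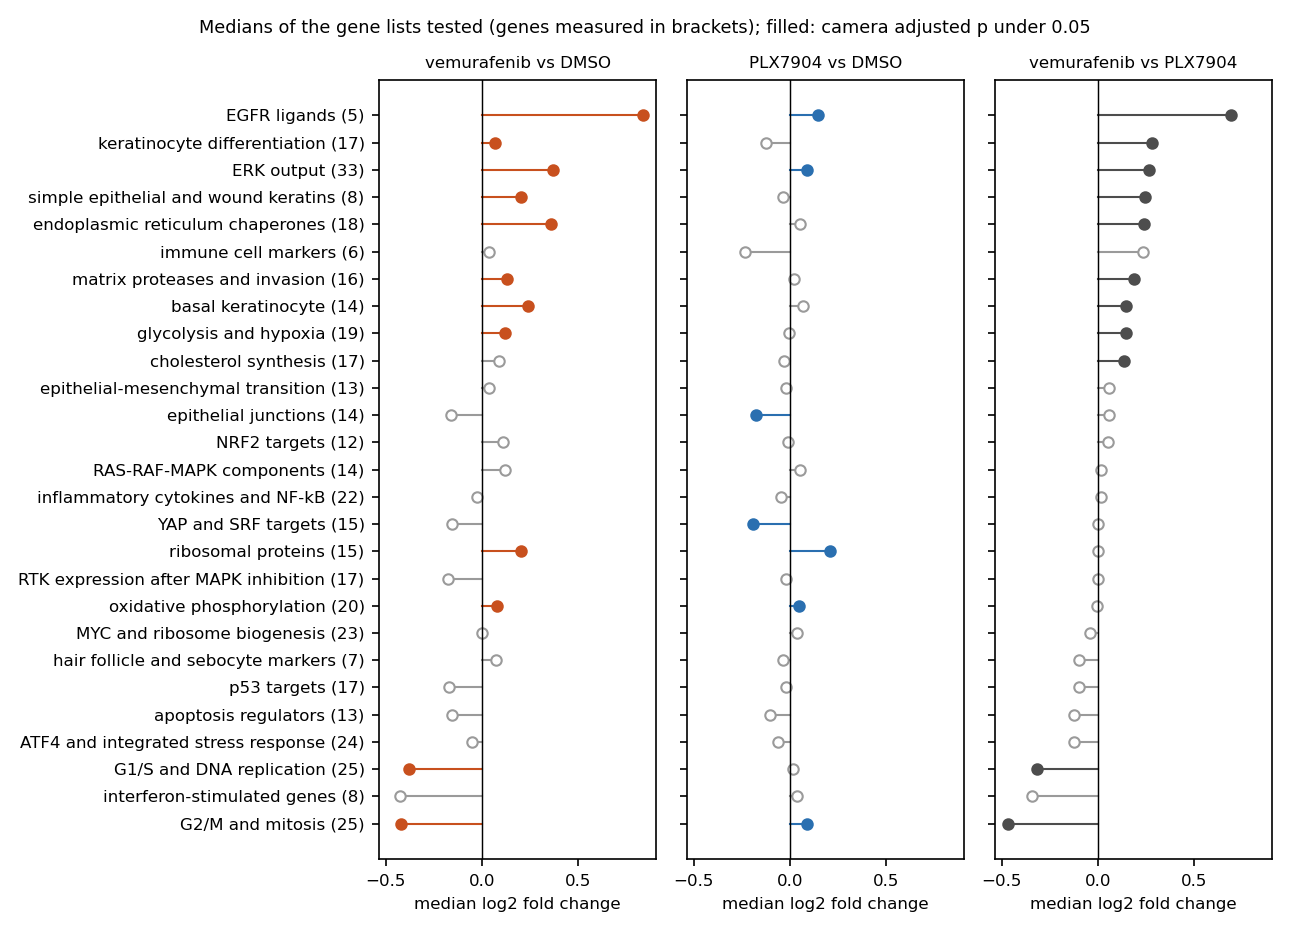
Median log2 fold change of the measured members of each tested gene list in the comparisons of vemurafenib with DMSO, PLX7904 with DMSO and vemurafenib with PLX7904. The ligands of the EGF receptor family and ERK output lie at 0.84 and 0.37 with vemurafenib and at 0.15 and 0.09 with PLX7904. The G2/M genes lie at -0.42 and 0.09.

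The third comparison set the compounds against each other at the same dose and time, 2 arrays each, and does not use the DMSO array for its fold changes. ERK output genes were higher with vemurafenib: 18 of 33 were higher and 0 lower (22 and 0 when adjusted over the list alone), at a median log2 difference of 0.27. Dusp5 was 3.05-fold higher (95% interval 2.67 to 3.49, adjusted p = 3.93e-06), Egr1 2.62-fold (2.13 to 3.21), Spry2 1.80-fold (1.56 to 2.09), Plaur 1.72-fold (1.53 to 1.94) and Phlda1 1.44-fold (1.32 to 1.57). Of 5 ligands of the EGF receptor family 4 were higher, and all 5 when adjusted over the list alone, at a median of 0.69. Hbegf was 1.80-fold higher (1.65 to 1.97), Tgfa 1.62-fold (1.42 to 1.84), Nrg1, which binds ERBB3, 1.45-fold (1.22 to 1.74) and Ereg 1.44-fold (1.28 to 1.61). Btc missed the threshold at 1.82-fold (1.22 to 2.72, adjusted p = 0.0531). Camera gave adjusted p = 4.6e-11 for ERK output, with adjusted p = 0.179 with an estimated correlation. For the ligands it gave 1.22e-06, with adjusted p = 0.184 with an estimated correlation. The compounds did not differ detectably in Myc (1.10 times lower, interval 0.97 to 1.25) or Ccnd1 (1.05-fold higher, 0.96 to 1.15). With the mean of all probe sets the calls of Spry2 (log2 0.37, adjusted p = 0.233), Tgfa (log2 0.52) and Egr3 ended, the latter turning from 1.08 to -0.18.

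Cell cycle genes were lower with vemurafenib than with PLX7904. Of 25 G2/M genes 22 were lower (24 when adjusted over the list alone) and none lay above 0, at a median log2 difference of -0.47. Nusap1 was 1.72 times lower (95% interval 1.53 to 1.93) and Kif11 1.70 times lower (1.43 to 2.02). Of 25 G1/S genes 15 were lower (17 when adjusted over the list alone), at a median of -0.32. Rfc4, a clamp loader subunit, was 1.63 times lower (1.44 to 1.85) and the primase Prim1 1.55 times lower (1.39 to 1.72). Camera gave adjusted p = 3.6e-16 and 2.06e-09, and for both lists adjusted p = 0.179 with an estimated correlation. Cdkn1a was 2.26-fold higher (1.89 to 2.70) while the p53 target list, with 3 higher and 4 lower (3 and 5 when adjusted over the list alone), did not pass (adjusted p = 0.567). The call of Nusap1 ended with the mean of all its probe sets (log2 -0.93).

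Endoplasmic reticulum chaperones were higher with vemurafenib, 9 of 18 with 0 lower (11 when adjusted over the list alone; median 0.24, adjusted p = 1.7e-07, and adjusted p = 0.179 with an estimated correlation). Sdf2l1 was 1.57-fold higher (95% interval 1.37 to 1.80) and the co-chaperone Dnajb9 1.5-fold (1.30 to 1.72). Of 16 matrix protease genes 6 were higher and 1 lower (8 and 1 when adjusted over the list alone; adjusted p = 6.5e-04, and adjusted p = 0.407 with an estimated correlation). Mmp10 was 2.71-fold higher (2.24 to 3.27), Plau 2.17-fold (1.77 to 2.67) and Timp3 2.59 times lower (2.04 to 3.29). Of 17 differentiation genes 4 were higher and 0 lower, also over the list alone (median 0.28, adjusted p = 7.1e-04, and adjusted p = 0.315 with an estimated correlation), with Sprr1a at 3.11-fold (2.67 to 3.62) and Ivl at 2.13-fold (1.83 to 2.50). Of 14 basal keratinocyte genes 6 were higher and 1 lower (7 and 1 when adjusted over the list alone; adjusted p = 8.1e-04, and adjusted p = 0.269 with an estimated correlation). The lower gene was the keratin Krt5, whose call ended without the filter on signal (log2 -0.234, limma adjusted p = 0.064). Lamb3 was 2.08-fold higher (1.86 to 2.33) and Lama3 2.18-fold (1.99 to 2.39), the latter turning to log2 -0.17 with the mean of all its probe sets. The basal list's median of 0.14 fell to about 0 (-8.9e-05) without probe sets that may match several transcripts. With the mean of all probe sets the basal list did not pass (median 0.12, adjusted p = 0.0791). Of 8 simple and wound keratins 4 were higher and 0 lower, also over the list alone (adjusted p = 0.0016, and adjusted p = 0.377 with an estimated correlation). With fry the matrix protease (adjusted p = 0.0874), differentiation (adjusted p = 0.0604) and simple and wound keratin lists (adjusted p = 0.0574) did not pass.

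Genes of glycolysis and hypoxia (4 of 19 higher, 6 higher and 2 lower when adjusted over the list alone) had adjusted p = 0.0226, and adjusted p = 0.343 with an estimated correlation. Its median of 0.14 was 0.175 after quantile normalization (adjusted p = 0.0658), 0.177 after cyclic loess (adjusted p = 0.0514), 0.116 with the filter at the 75th percentile (adjusted p = 0.0525) and 0.144 without probe sets that may match several transcripts (adjusted p = 0.0716), and its call ended in each. Ndrg1 was 1.96-fold higher (95% interval 1.74 to 2.20) and Vegfa 1.45-fold (1.24 to 1.70). Cholesterol synthesis genes (1 of 17 higher, 4 higher and 1 lower when adjusted over the list alone) had adjusted p = 0.030, and adjusted p = 0.343 with an estimated correlation. Its median of 0.13 was 0.086 after quantile normalization (adjusted p = 0.105), 0.105 after cyclic loess (adjusted p = 0.0787), 0.0291 with the mean of all probe sets (adjusted p = 0.38) and 0.0798 without probe sets that may match several transcripts (adjusted p = 0.0519), and its call ended in each. It did not pass without the intensity trend (adjusted p = 0.0541) or with the filter at the 75th percentile (adjusted p = 0.0696), nor without vemurafenib replicate 1 (median 0.13, adjusted p = 0.0929), vemurafenib replicate 2 (0.10, adjusted p = 0.123) or PLX7904 replicate 1 (0.11, adjusted p = 0.0708). Of 22 inflammatory genes 6 were higher and 4 lower (6 and 6 when adjusted over the list alone; adjusted p = 0.916), with Ccl2 2.71 times lower (2.40 to 3.07) and Il23a 1.86-fold higher (1.57 to 2.20). No difference between the compounds was detected for ribosomal protein genes (median -0.0016, 0 of 15 called, adjusted p = 0.916) or oxidative phosphorylation (0 of 20 called, adjusted p = 0.916). After cyclic loess the ribosomal list was lower with vemurafenib (median -0.05, adjusted p = 0.038). The other 12 lists tested, among them targets of YAP and SRF (2 higher, 2 lower, adjusted p = 0.916) and interferon-stimulated genes (2 of 8 lower, 0.198), did not pass, at adjusted p from 0.198 to 0.916. The interferon-stimulated list passed as lower without the intensity trend (-0.34, adjusted p = 0.0387), RAS-RAF-MAPK components as higher with the filter at the 75th percentile (0.197, adjusted p = 0.0481), and YAP and SRF targets with fry (adjusted p = 0.0237). For NRF2, inflammatory and YAP and SRF genes the mean was below 0 and the median above it, and for oxidative phosphorylation both were below 0 while camera pointed up. Of the aryl hydrocarbon receptor targets Cyp1b1 was 2.95 times lower (2.48 to 3.49), a call that ended with the mean of all its probe sets (log2 -1.30), and the ADP-ribosyltransferase Tiparp was 1.25-fold higher (1.12 to 1.39), a call that ended without vemurafenib replicate 1 (log2 0.28).

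In all, 698 genes were higher and 745 lower with vemurafenib than with PLX7904, 13.3% of those tested, and 75 and 63 of them differed at least 2-fold. Fgf18, a fibroblast growth factor, was 4.21-fold higher (95% interval 3.41 to 5.21), Il24 3.94-fold (3.38 to 4.6), Trex2 3.70-fold (2.97 to 4.62) and Crct1, a gene of the epidermal differentiation cluster, 3.77-fold (2.79 to 5.10). Sostdc1 was 5.74 times lower (4.94 to 6.67) and Ptn 4.92 times lower (3.64 to 6.64). Fas was 5.37 times lower (2.86 to 10.1) and Epha7, an ephrin receptor, 3.46 times lower (2.48 to 4.84). The largest fall, of Scrt1, was 7.79 times (3.16 to 19.2) at a mean signal of 48.0, and its call ended without PLX7904 replicate 2 (log2 -2.89). Median centring gave 839 higher and 585 lower genes, 58.9% higher in place of 48.4%. Without the intensity trend 21 genes were higher and 14 lower, and 34 of the 1443 calls were kept. Without vemurafenib replicate 1 the counts were 452 and 448, and without PLX7904 replicate 2 they were 605 and 485.

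**Figure D3:**
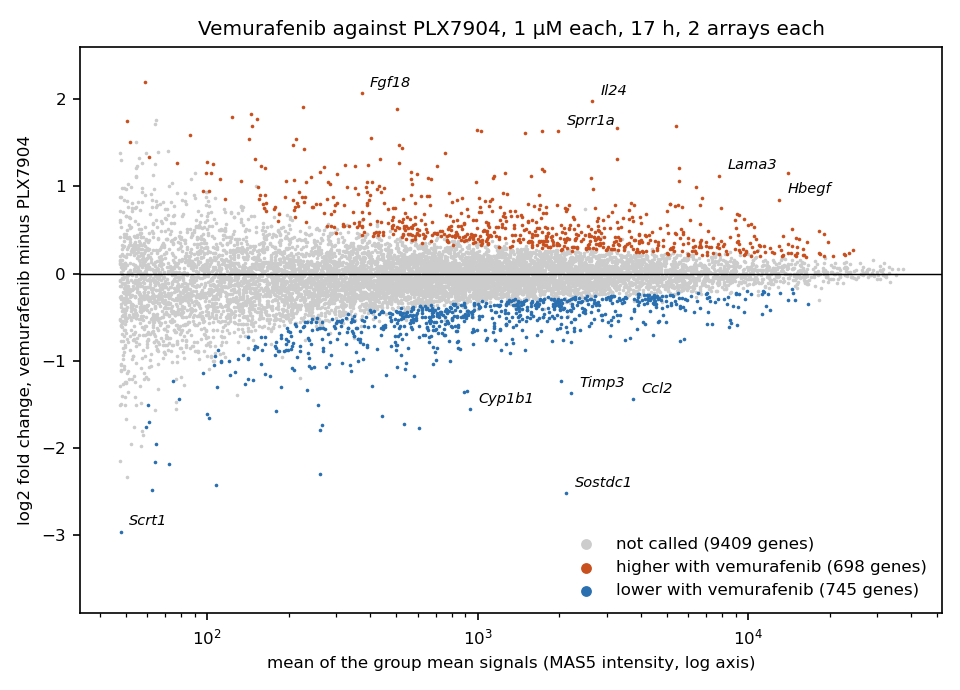
Log2 difference between vemurafenib and PLX7904 (2 arrays each) against mean signal on a log axis, 1 point per gene tested, with the called genes coloured. Called genes lie on both sides, 698 higher and 745 lower, with Il24 at 1.98 and Sostdc1 at -2.52.

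Of the 589 genes higher with vemurafenib than with DMSO, 451 (76.6%) were also higher than with PLX7904, and of the 565 lower genes 424 (75%) were also lower. Both comparisons use the vemurafenib arrays, so some overlap arises with no effect at all. In 100 simulations of unchanged groups, lists of the same sizes ranked farthest from 0 shared on average 135 higher and 136 lower genes and at most 156 and 151, while independent lists would share 37.9 and 38.8. The simulated values leave out real effects and the independent ones the shared arrays, so the excess over either is not a measure of a shared effect. The comparisons of the 2 compounds with DMSO share the DMSO array. Across all genes 68% of fold changes from DMSO had the same sign with both compounds, where unchanged groups simulated against 1 shared control gave a mean of 73.2%. The fold changes correlated at r = 0.506 against a simulated mean r of 0.668. Their covariance was 0.0515 against a simulated mean of 0.0366 and a simulated maximum of 0.0402 over 100 simulations. Genes are not independent replicates, and with 1 DMSO array the control could not be split.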

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

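The tests on spiked-in controls and on RNA degradation below were chosen only after the result was seen.

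The spiked-in cre control, a bacteriophage sequence added during processing and used in no comparison, read 0.203 (log2) higher on the PLX7904 arrays and 0.201 higher on the vemurafenib arrays than on the DMSO array, a signal in data outside the main measurement. The 3' probe set for 18S ribosomal RNA, also outside the main measurement, read 11574 on PLX7904 replicate 2 (11574.4 before rounding), above 8268 on the DMSO array and 7378 to 8852 on the other treated arrays.

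Ribosomal protein genes were higher on all treated arrays taken as groups, at a median log2 difference of 0.21 from DMSO with either compound. A signal-dependent difference of the DMSO array may account for this. After quantile normalization the list no longer passed camera, with adjusted p = 0.399 for PLX7904 and 0.763 for vemurafenib. These genes are bright, the dimmest at a mean signal of 2180. Quantile normalization makes the bright ends of all arrays equal and could also remove a real rise, so the lost call cannot decide. After cyclic loess it still passed for PLX7904, at a smaller median of 0.09 (adjusted p = 8.9e-07). Spiked-in controls, which do not come from the cells, bear on this too: the 11 hybridization controls as bright as these genes were higher on the treated arrays by a median of 0.072 with PLX7904 and 0.109 with vemurafenib, but the 4 cre probe sets, the brightest of them, stood 0.142 to 0.203 above DMSO. The 4 equally bright poly-A controls stood 0.271 higher with PLX7904 and 0.214 with vemurafenib, as far as the list or farther, while 20 dimmer poly-A controls stood 0.298 and 0.173 higher, so that their shift was not limited to bright signals. A rise of these transcripts under both compounds stays open, with the list's median at percentile 96.1 of random lists matched on signal for vemurafenib and 99.9 for PLX7904. So does an effect of the vehicle, whose concentration in the control relative to the treated cultures is not settled by the labels. With 1 DMSO array the explanations cannot be told apart.

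ERK output genes were slightly higher with PLX7904 than with DMSO, at a median of 0.09. The signal-dependent difference of the DMSO array leaves part of it: the median was 0.0596 after quantile normalization (adjusted p = 0.0164) and 0.0708 after cyclic loess (adjusted p = 0.0138). Gene-by-gene error of the DMSO array cannot be excluded. The 712 genes called higher with vemurafenib than with PLX7904 from the 4 treated arrays alone had a median PLX7904 minus DMSO difference of 0.0155, at percentile 95.9 of matched random lists, just under their upper bound of 0.0165, but the 729 genes called lower stood at 0.00484, percentile 98.3, so that the value is not specific to genes raised by vemurafenib, and choosing genes this way pushes the first value down and the second up. Whether PLX7904 weakly raises ERK output or the DMSO array reads low for these genes cannot be told apart here. The vehicle concentration of the control is open too, and an effect of it was not tested.

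G2/M genes were lower on the vemurafenib arrays, and here the tables argue against both technical explanations tested. After quantile normalization or cyclic loess the median difference from PLX7904 was at least 0.46 in size (-0.46, adjusted p = 2.01e-17 and 9.31e-18), which argues against a signal-dependent difference between the arrays. A large difference in RNA degradation is argued against by the 3' to 5' ratios of control transcripts, which differed by -0.0162 (log2) between the vemurafenib arrays and the other 3. These controls, Gapdh and beta-actin, are very bright. Their 3' probe sets had mean signals of 20983 and 32028, where the highest 98th percentile of an array was 9107. A small difference in degradation could be missed with them. A lower share of cycling cells under vemurafenib is a hypothesis suggested by these same data, with cell numbers not analysed here.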

How the results depend on the processing

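The arrays are few and the counts of calls depend on how the variance is modelled. Without an intensity trend 26 genes were higher and 17 lower for vemurafenib against DMSO, and 21 and 14 for vemurafenib against PLX7904. Causes were not tested except where stated. Of the values for the ERK, ligand and cell cycle lists under the alternatives, 201 stayed on their side of the threshold and 19 lost the threshold. Among genes selected by the naming rule 4533 values stayed, 511 lost and 68 gained the threshold and 9 reversed. Among other lists 1153 stayed, 73 lost, 19 gained and 5 reversed. A change of sign counted as reversed only where the value passed in the main fit or the alternative, and otherwise as staying. So the basal keratinocyte median for PLX7904 against DMSO, 0.069 in the main fit and -0.012 after quantile normalization, counted as staying. Dim signal limits precision, since no measure of signal over background was used.

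With no filter, and so more dim genes tested, vemurafenib against DMSO gave 366 and 291 genes, 478 were lower than with PLX7904, and the ligands lost their call with PLX7904 (0.103, adjusted p = 0.163). With the filter at the 75th percentile PLX7904 against DMSO gave 1 and 2 genes, and its ligands (0.125, adjusted p = 0.058) lost their call. With the mean of probe sets the counts were 267 and 176 for vemurafenib against DMSO and 340 and 320 against PLX7904, and the ligands with PLX7904 (0.103, adjusted p = 0.341) lost their call. Against DMSO Rrm1 turned to 0.103, Sc5d to -0.38 and Atp5c1 to -0.0939, and against PLX7904 Egr3 turned to -0.177, Trp53inp1 to -0.263, Sc5d to -0.443 and Lama3 to -0.173. Without probe sets that may match several transcripts PLX7904 gave 1 and 2 genes, the basal keratinocyte median turned to -0.0782 (DMSO) and -8.88e-05 (PLX7904), and Fgfr1 to 0.0697 and Atp5c1 to -0.464 against DMSO. Quantile normalization turned the ribosomal median to -0.0041 and oxidative phosphorylation to -0.0507, and cyclic loess the latter to -0.0395, for vemurafenib against DMSO. Robust fitting gave 1 and 2 genes for PLX7904.

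At an adjusted p under 0.10, 955 genes were lower than with DMSO and 1141 lower than with PLX7904 under vemurafenib, and PLX7904 gave 1 and 2. At 2-fold the counts were 103 and 91, and 75 and 63. With an estimated correlation no list passed. That choice leaves the median log2 fold changes as they were: ERK output 0.368, ligands 0.838, G1/S -0.381 and G2/M -0.42 for vemurafenib against DMSO. For PLX7904 the medians were 0.0883 for ERK output, 0.146 for ligands and 0.0885 for G2/M. Between the compounds the 4 medians were 0.266, 0.692, -0.317 and -0.468. With fry the ligands (median 0.146, adjusted p = 0.119) and G2/M (median 0.0885, adjusted p = 0.185) lost their calls with PLX7904.

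The replicate numbers share only a number: deviations of same-numbered arrays correlated at r = -0.00711. With a replicate block PLX7904 against DMSO gave 2 and 2 genes, and its G2/M median of 0.0836 lost the threshold (adjusted p = 0.0516), as did keratinocyte differentiation for vemurafenib against DMSO (0.0498, adjusted p = 0.0791) and epithelial junctions for PLX7904 (-0.182, adjusted p = 0.0636). It changed no other list call and moved no other count by over 1.5 times.

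Leaving out each treated array in turn, with a lone array assumed to vary like the others, vemurafenib against DMSO gave 433 to 785 higher and 447 to 723 lower genes, PLX7904 0 to 14 and 0 to 15, and vemurafenib against PLX7904 452 to 687 and 448 to 667. ERK output ranged from 0.362 to 0.42, ligands 0.835 to 0.842, G1/S -0.416 to -0.381 and G2/M -0.42 to -0.376 for vemurafenib. For PLX7904 they were 0.0883 to 0.113, 0.132 to 0.207, 0.0143 to 0.0362 and 0.0696 to 0.105, and between the compounds 0.239 to 0.292, 0.647 to 0.753, -0.382 to -0.352 and -0.485 to -0.423. Ligands and G2/M with PLX7904 lost the threshold without PLX7904 replicate 2 (adjusted p = 0.0624 for each).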

Other observations

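The genes in this part lie outside the lists and were chosen after their values were seen. Errfi1, which encodes a feedback inhibitor of the EGF receptor, was 2.98-fold higher with vemurafenib than with DMSO (95% interval 2.63 to 3.37, adjusted p = 5.32e-06) and 2.32-fold higher than with PLX7904 (2.10 to 2.56), alongside the receptor's ligands. Myc did not pass in any comparison, while Mxd1 and Mxi1, whose products compete with MYC for its partner MAX, were 2.50-fold (1.70 to 3.66) and 1.94-fold (1.61 to 2.33) higher with vemurafenib than with DMSO. The cyclin Ccng2, found in cells leaving the cycle, was 2.10-fold higher (1.79 to 2.46). Besides Ivl and Sprr1a, other cornified envelope genes were higher: Lce3c 2.36-fold (1.84 to 3.03) and Sprr2h 1.82-fold (1.58 to 2.11). Both belong to families of similar genes, and their probe sets carry a suffix for sequence shared between transcripts.

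Bmp2, a ligand of the BMP family, was 2.15-fold higher with vemurafenib than with DMSO (95% interval 1.81 to 2.54), while Id2 and Smad6, both induced by BMP signals in many cells, were 2.39 (2.06 to 2.77) and 2.28 (1.73 to 3.01) times lower, and the antagonist Sostdc1 was 5.83 times lower. Ifi209 and Ifi202b, DNA sensors of the p200 family, were 3.52-fold (3.01 to 4.13) and 3.24-fold (2.82 to 3.72) higher with vemurafenib, whereas the interferon-stimulated list had a median of -0.43 and passed only without the intensity trend (adjusted p = 0.0175). With PLX7904 these 2 genes stood at 1.14-fold (adjusted p = 0.804) and 1.02-fold (adjusted p = 0.986) of DMSO.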
